A study of Mus musculus with 9 samples.

How the data were processed

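The series holds 9 arrays of mouse thymocyte RNA, 1 mouse each, with 2 control, 3 pre-transformed and 4 tumour samples. Per the labels, sorted DP thymocytes gave 0.1 µg RNA for an amplification kit and tumours 2.5 µg for the standard biotin labelling protocol. The authors deposited 1 table of MAS5 signal intensity per probe set on a linear scale, and the version of MAS5 is not given in the sources used here. Checked on the values, each array had been scaled so that its mean without the lowest and highest 2% of 45101 probe sets was 100. Values were rounded to 0.1, 218 of them were 0, and median signals were 9.9 to 15.2. Calls of presence or absence were not used here. Signals of 27 probe sets for bacterial transcripts that were not added reached 2.4 to 5 on sorted arrays and 7.8 to 13.9 on tumour arrays, which marks the background. Background was thus higher on tumour arrays, which limits what a rise from a dim signal in tumours can show.

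Signals were taken to log2 with values of 0 set to 0.1 and no further normalization. The 64 control probe sets were left out, which left 45037. Probe sets were kept if at or above the median of their array on at least 2 arrays (26421 probe sets). Of all probe sets 34945 named 1 gene, 932 named several and 9160 named none in the tables used here. Each gene was represented by its kept probe set with the highest mean, which gave 11644 genes tested, with 34 values at the floor among them. Group signals are geometric means, and SD values are on the log2 scale.

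Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend of the spread with signal). Pre-transformed and control arrays were fitted alone, and both tumour comparisons were fitted on all 9 arrays. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the genes tested. Replicate numbers name different mice in each group, so that no pairing was used. A total of 33 gene lists, of pathways, stages and markers of other cells, held 665 genes, of which 609 were named on the array and 538 tested. Lists were tested with camera (preset correlation 0.01, and again with an estimated correlation) and with fry, and adjusted over the 33 lists of a comparison. The β-actin and Gapdh 3′ and 5′ probe sets were compared between tumours and sorted cells by an exact permutation test. Genes changed before transformation and called in the same direction in tumours against controls were counted, with 100 simulations of groups that do not differ from these controls. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

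The groups, tests, lists, main alternatives and the rule for named genes were fixed before the data were examined. The rule took the 10 largest rises and falls among called genes whose arrays did not overlap between groups and whose higher mean was at least 22.2, with sex-linked genes, receptor and immunoglobulin segments, haemoglobins and unnamed transcripts left out. It also took 2 to 4 members of each list with the smallest p or largest change, and a fixed set of genes of the pathway and stage. Folds given as at least a value were chosen after seeing the data: the dimmer group was set to the 65th percentile of its arrays (28.5 to 44.6), or left at its own value if higher, and no fold is given where both groups were dim.

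The method was tested on 20 simulated sets with 200 of 11644 genes changed. Noise was drawn as normal values whose spread came from fits with the same kind of trend, so that the sets do not test the trend itself. The tumour comparisons called 54.9% and 45.7% of genes, far more than were changed here, so the rates below may not hold for them. For a log2 size of 1, 61.6% (49.3 to 73.1% over the sets) were recovered for pre-transformed against control, 33.6% (20.9 to 44.8%) for tumours against pre-transformed and 22.5% (8.96 to 32.8%) for tumours against control. False calls made up 6.65% (2.63 to 11.1%), 5.8% (2.56 to 11.7%) and 3.23% (0 to 8.06%) of calls, and no call of a changed gene had the wrong direction. Alternatives were no filter, a stricter filter, quantile normalization, median centring, an added offset of 1.2, every probe set, the mean of probe sets, probe sets without cross-hybridisation suffixes, no trend, robust variance, array weights, a 2-fold minimum, replicate number as a block, other sets of arrays in the fit and each array left out. A common floor of 40.5, tumour 2 as the only tumour and a different control array for each comparison against controls were added after seeing the data.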

Results

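Gene expression was measured in mouse thymocytes in which β-catenin, the transcriptional effector of canonical Wnt signalling, was kept active from the CD4+CD8+ double-positive (DP) stage onward by a Cre recombinase under Cd4 control. RNA from 9 C57Bl/6 mice was read on 1 oligonucleotide array each. The control group held sorted DP thymocytes of 2 Cre-negative mice aged 6 weeks. The pre-transformed group held sorted DP thymocytes of 3 Cre-positive mice of the same age, whose thymi were of normal size. The tumour group held thymic tumours of 4 Cre-positive mice aged 28, 26, 23 and 21 weeks (tumours 1 to 4). Sorted cells were over 98% DP, and the unsorted tumours held at least 95% DP cells. The number of arrays limits the precision of every value below. Sorted cells were labelled from 0.1 µg RNA with an amplification kit and tumours from 2.5 µg by the standard protocol, so that labelling, sorting and age all went with the tumour group. Likewise, Cre was present in each mouse with active β-catenin and absent from each control. By their Xist and Y-linked signals, pre-transformed 1 and tumour 4 came from male mice. All other arrays, both controls among them, came from females, and sex was part of no fit.

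Tumour arrays stood apart from both sets of sorted cells. Rank correlations across the 11644 genes tested, which are not independent replicates, were 0.991 between the control arrays, 0.983 to 0.988 among pre-transformed arrays, 0.979 to 0.984 between control and pre-transformed arrays, and 0.916 to 0.952 among tumours. Between tumours and sorted cells they were 0.793 to 0.863. The β-actin transcript showed more loss of signal toward its 5′ end in tumours, with a 3′ to 5′ log2 ratio of 0.81 (SD 0.28, n = 4) against 0.26 (SD 0.05, n = 5) in sorted cells. That difference had the smallest p that the 126 splits allow (exact two-sided permutation test, p = 0.00794). For Gapdh the ratio was −0.31 (SD 0.19, n = 4) in tumours and −0.20 (SD 0.12, n = 5) in sorted cells (exact two-sided permutation test, p = 0.317). Ctnnb1, which encodes β-catenin itself, read 2421 and 2753 on the control arrays, 2523 to 2775 on the pre-transformed arrays and 2241 to 3726 on the tumour arrays. With the main settings it passed the test in no comparison (adjusted p = 0.85 between both sorted groups). Among the alternatives it was called higher in tumours in 3 settings against pre-transformed cells and in 2 against controls. Its log2 change ran from −0.205 to 1.098 and from −0.098 to 1.288 over the alternatives.

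Pre-transformed and control DP thymocytes were compared to ask what active β-catenin changes in DP cells before tumours form. Cecr2, which encodes a bromodomain protein of chromatin remodelling complexes, rose from a mean signal of 5.98 (SD 0.41 on the log2 scale, n = 2) to 922 (SD 0.28, n = 3), at least 22.6-fold (adjusted p = 4.66e-06). Cd44, the hyaluronan receptor and a Wnt target in several tissues, rose 8.99-fold from 61.4 (SD 0.33, n = 2) to 551 (SD 0.41, n = 3; adjusted p = 0.0015). Of 27 measured genes of mitosis 10 fell, among them the survivin gene Birc5 and the cyclin gene Ccna2 (722 to 344 and 620 to 299.6). Myc and the recombination genes Rag1 and Rag2 did not pass. Among the 11644 genes, 129 rose and 61 fell, 82 of these 190 by at least 2-fold. With every array centred on its median the split was 96 higher and 101 lower.

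Beside Cecr2 and Cd44, the largest rises included Prag1, which encodes a pseudokinase, at least 4.32-fold (adjusted p = 0.0015), and Esrp2, a splicing factor of epithelial cells, from 86.6 to 619 (log2 change 2.84 ± 0.20 SE, adjusted p = 0.0015). Cadm4, which encodes a cell adhesion molecule, rose at least 1.67-fold. The homeobox gene Nkx2-4 rose at least 1.32-fold and the mitochondrial carrier gene Slc25a18 at least 1.11-fold from dim control means. The largest falls included the proapoptotic Bmf (255 to 105, log2 change −1.28 ± 0.19 SE, adjusted p = 0.0241), the neuropilin gene Nrp1 (297 to 134, log2 change −1.15 ± 0.18 SE, adjusted p = 0.0267), Zmiz1, a partner of Notch1 in transcription (684 to 293, log2 change −1.22, adjusted p = 0.0106), and Eya2, which fell by at least 1.41-fold.

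Wnt target genes moved in part. Of 15 measured, 2 rose over all genes tested and 3 rose adjusted over the list alone. The pair were Cd44 and Dact1, a Dishevelled antagonist, which rose at least 3.71-fold (adjusted p = 0.00186). Axin2, a widely used readout of the pathway, read 81.5 in controls (SD 0.31, n = 2) and 138 in pre-transformed cells (SD 0.03, n = 3), with a log2 change of 0.76 ± 0.17 SE that missed the threshold (adjusted p = 0.0667). Lef1 had a log2 change of −0.15 (adjusted p = 0.528). The list as a whole was not called (adjusted p = 0.294, and adjusted p = 0.709 with an estimated correlation). Of 25 Wnt pathway components limma called 0, and 4 had an unadjusted p under 0.05, all higher.

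All 27 measured mitosis genes passed adjusted over the list alone, against 10 over all genes tested, with a list median of −0.86 on the log2 scale. Birc5 had a log2 change of −1.07 ± 0.14 SE (adjusted p = 0.0167), Ccna2 of −1.05 ± 0.14 SE (adjusted p = 0.0185) and the kinetochore gene Cenpf of −0.87 ± 0.14 SE (adjusted p = 0.0273). The list was called by camera at adjusted p = 8.26e-26, but had an adjusted p = 0.684 with an estimated correlation. By fry the mitosis list had an adjusted p = 0.238, and fry called no list in this comparison. Tpx2, a spindle assembly factor, fell by 1.10 on the log2 scale on its brightest probe set (adjusted p = 0.0326), while the mean of its probe sets gave 0.31 (adjusted p = 0.781; 0.0126 to 0.781 over the alternatives). Of 27 DNA replication genes, 1 passed over all genes tested, the cyclin gene Ccne1, which rose by a log2 change of 0.83 (adjusted p = 0.0488) and was not called with quantile normalization or median centring. Without pre-transformed 2, 8 were lower over all genes tested. Adjusted over the list alone, 18 were lower, including the ribonucleotide reductase gene Rrm1 at −0.76 (adjusted p = 0.0503 over all genes). That list was called as lower (adjusted p = 2.23e-10), with an adjusted p = 0.684 with an estimated correlation. Mki67 read 1345 in controls and 820 in pre-transformed cells (log2 change −0.72 ± 0.14 SE, adjusted p = 0.0515).

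Of 37 Myc targets 1 fell, the ribosome biogenesis gene Wdr12 (log2 change −0.90, adjusted p = 0.0099), with 1 lower adjusted over the list alone. The list median was −0.20 (adjusted p = 0.000292, and adjusted p = 0.684 with an estimated correlation). Of 26 ribosomal protein genes limma called 0 over all genes tested and 3 as lower adjusted over the list alone, with 6 lower at an unadjusted p under 0.05 (list adjusted p = 0.000131, and adjusted p = 0.715 with an estimated correlation). Of 20 cell cycle regulators limma called 0 over all genes tested and 0 adjusted over the list alone, with 7 lower at an unadjusted p under 0.05 (list adjusted p = 0.0365, and adjusted p = 0.684 with an estimated correlation). Myc itself had a log2 change of 0.05 (adjusted p = 0.957).

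In the DP program and the Notch pathway no gene was called over all genes tested. Median centring gave 2 Notch pathway genes and 1 DP gene as lower, and quantile normalization 1 DP gene as higher. Of 27 DP thymocyte genes limma called 0, with 5 higher and 3 lower at an unadjusted p under 0.05 and 4 higher and 2 lower adjusted over the list alone. Rag1 had a log2 change of 0.08, Rag2 of −0.03, Dntt of 0.10, Cd4 of 0.46 (adjusted p = 0.135) and Cd8a of 0.09. Of 21 Notch pathway genes limma called 0, with 2 higher and 3 lower at an unadjusted p under 0.05 and 1 higher and 3 lower adjusted over the list alone. Notch1 read 731 in controls and 462 in pre-transformed cells (log2 change −0.66 ± 0.14 SE, adjusted p = 0.0667), Notch3 had a log2 change of −0.58 (adjusted p = 0.136), and Ptcra, a Notch target that encodes the pre-TCR α chain, read 344 and 230 (adjusted p = 0.0672). Single genes of other lists rose: the ubiquitin ligase subunit gene Fbxw7 (log2 change 0.70, adjusted p = 0.0267), the PI3K regulatory subunit gene Pik3r5 (0.80, adjusted p = 0.0376), the chemokine receptor gene Cxcr4 (0.64, adjusted p = 0.0495) and the antiapoptotic Bcl2l2 (at least 2.04-fold). Markers of other cells passed in 1 of 19 myeloid genes (Itgam, higher, with means under the 65th percentile of the arrays, here called dim, in both groups) and 1 of 9 B cell genes (Ighm, lower by a log2 change of −0.66, adjusted p = 0.0299).

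All 190 genes had arrays that did not overlap between the groups, as did 4224 of all genes, where chance gives 20% of genes. The count fell to 74 with no filter on dim probe sets, 82 with a 2-fold minimum, 15 with a common floor for dim values, 6 with all 9 arrays in the fit and 1 without the trend of the spread with signal, rose to 431 with array weights, and was 28 without control 1, 17 without control 2, 19 without pre-transformed 3 and 291 without pre-transformed 2. Of the 20 called genes named by rule, Cecr2 alone passed under each of these settings, and the count of lower mitosis genes ran from 0 to 15 with 1 array left out, was 0 with the common floor and 16 with median centring.

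Tumours and pre-transformed DP thymocytes were compared to ask what sets apart transformed cells from cells of the same genotype before transformation. Myc rose 18.5-fold, from a mean signal of 74.9 (SD 0.58 on the log2 scale, n = 3) to 1385 (SD 0.26, n = 4; adjusted p = 7.56e-06). Genes that Myc is known to drive rose with it (36 of 37), as did genes of mitosis (27 of 27), DNA replication (25 of 27) and ribosomal proteins (26 of 26, or 16 higher and 1 lower with quantile normalization). Notch1 fell from 462 (SD 0.24, n = 3) to 21.0 (SD 0.35, n = 4), by at least 12.9-fold (adjusted p = 5.04e-06), and its target Ptcra from 230 (SD 0.12, n = 3) to 4.31 (SD 0.59, n = 4), by at least 6.42-fold. Rag1, Rag2 and other genes of the DP stage fell, while Cd4 and Cd8a stayed bright.

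**Figure D1:**
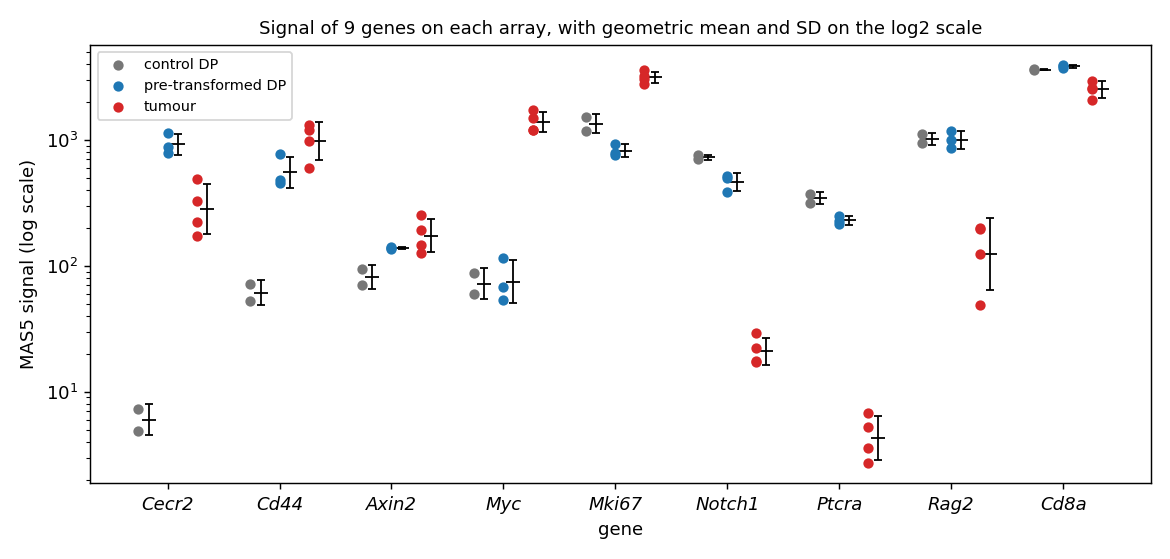
MAS5 signal (log scale) of Cecr2, Cd44, Axin2, Myc, Mki67, Notch1, Ptcra, Rag2 and Cd8a, with a point for each array and the geometric mean with its SD on the log2 scale for 2 control, 3 pre-transformed and 4 tumour arrays. Cecr2 averaged 5.98 in controls, 922 in pre-transformed cells and 280.4 in tumours, Myc 72.3, 74.9 and 1385, and Notch1 731, 462 and 21.0.

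In this comparison 2785 genes rose and 3607 fell among 11644, 4324 of them by at least 2-fold. Centring every array on its median moved the median change of all genes from −0.12 to 0.17 on the log2 scale and gave 3458 higher and 2613 lower genes; list medians below are relative to the all-gene median. The groups did not overlap for 6632 genes, where chance gives 5.71% of genes, and 6015 of these were among the 6392 called. Every list call by camera below rested on a preset correlation, and camera called no list in any comparison with an estimated correlation. In tumours against pre-transformed cells fry, which tests whether members move on balance one way, passed for some lists and not for others. It gave an adjusted p of 4.33e-05 for Myc targets and of 0.254 for T-ALL oncogenes.

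The largest rises held Igfbp7, a secreted protein of endothelial and stromal cells, at least 18.8-fold, and Wwc1, a regulator of Hippo signalling, at least 18.3-fold, from a signal of 3.42 to 799. Plekha8, a lipid transfer protein gene, rose at least 10.9-fold, Asns, which encodes asparagine synthetase, at least 9.5-fold (adjusted p = 7.14e-05), Fstl1 at least 7.3-fold, Mapk10 at least 5-fold and Shisa2, a modulator of Wnt and FGF receptors, at least 4.17-fold. The neutrophil gene S100a8 rose at least 2.72-fold and the macrophage gene Chil3 at least 1.37-fold, and both were near background in tumour 2. The largest falls held the interferon-inducible guanylate-binding protein gene Gbp8, from 2672 to 14.5, at least 58.1-fold, and Gbp6, at least 13.6-fold. Slc5a9, a sugar transporter gene, fell at least 24.2-fold, Clec2d, which encodes an NK receptor ligand, at least 23.3-fold (837 to 1.8, adjusted p = 5.04e-06), Plxdc1 at least 16.4-fold, Dnajc6 at least 10.8-fold and Prodh, which encodes proline dehydrogenase, at least 10.4-fold.

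Growth and division genes rose as groups. Among Myc targets the nucleolar gene Gnl3 went from 309.9 to 2007 (log2 change 2.69 ± 0.14 SE, adjusted p = 5.04e-06) and Ran, a GTPase of nuclear transport, from 1319 to 5609 (2.09 ± 0.11 SE). Adjusted over the list alone 36 were also higher, the median stood 1.97 above that of all genes, and the list had an adjusted p = 1.65e-17, or an adjusted p = 0.388 with an estimated correlation. Mitosis genes had a median 2.25 above that of all genes (27 adjusted over the list alone, adjusted p = 5.3e-16, or adjusted p = 0.388 with an estimated correlation). Among them Kif2c rose by a log2 change of 2.93 and Mki67 from 820 to 3142 (1.94 ± 0.14 SE, adjusted p = 1.09e-05). For DNA replication the median stood 1.80 above (25 adjusted over the list alone, adjusted p = 2.22e-11, or adjusted p = 0.388 with an estimated correlation), with Rfc4 at a log2 change of 2.45 and Mcm6 at 1.83. For ribosomal proteins it stood 1.07 above (26 adjusted over the list alone, adjusted p = 2.01e-11, or adjusted p = 0.396 with an estimated correlation), with Rpl35 at 1.36 and Rps2 at 1.34, but quantile normalization lowered the list median from 0.952 to 0.417, neither taken relative to all genes.

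Glycolysis genes followed, with 9 of 16 higher and 1 lower, also adjusted over the list alone (adjusted p = 0.00119, or adjusted p = 0.42 with an estimated correlation). Pgk1 rose from 978 to 4416 and the pyruvate kinase gene Pkm by a log2 change of 2.06, while the hexokinase gene Hk1 fell from 491 to 173.5. Of 27 genes of double-strand break repair 15 rose and 5 fell, against 15 and 6 adjusted over the list alone and 13 and 1 without pre-transformed 1 (adjusted p = 0.00314, or adjusted p = 0.407 with an estimated correlation). Those that rose included the checkpoint kinase gene Chek1 (log2 change 3.20), Rad54l (2.43) and Parp1 (1.81), and those that fell, named after their values were seen, were Lig4, Nhej1, Polm and Prkdc of end joining and Rad52. Of 20 cell cycle regulators 10 rose and 6 fell, against 11 and 6 adjusted over the list alone (adjusted p = 0.236, or adjusted p = 0.629 with an estimated correlation). Ccnd2 rose at least 1.79-fold (adjusted p = 0.000497) and Ccnd3 fell by 1.26 on the log2 scale (adjusted p = 0.0102), and the inhibitor gene Cdkn1b fell by 2.15.

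**Figure D2:**
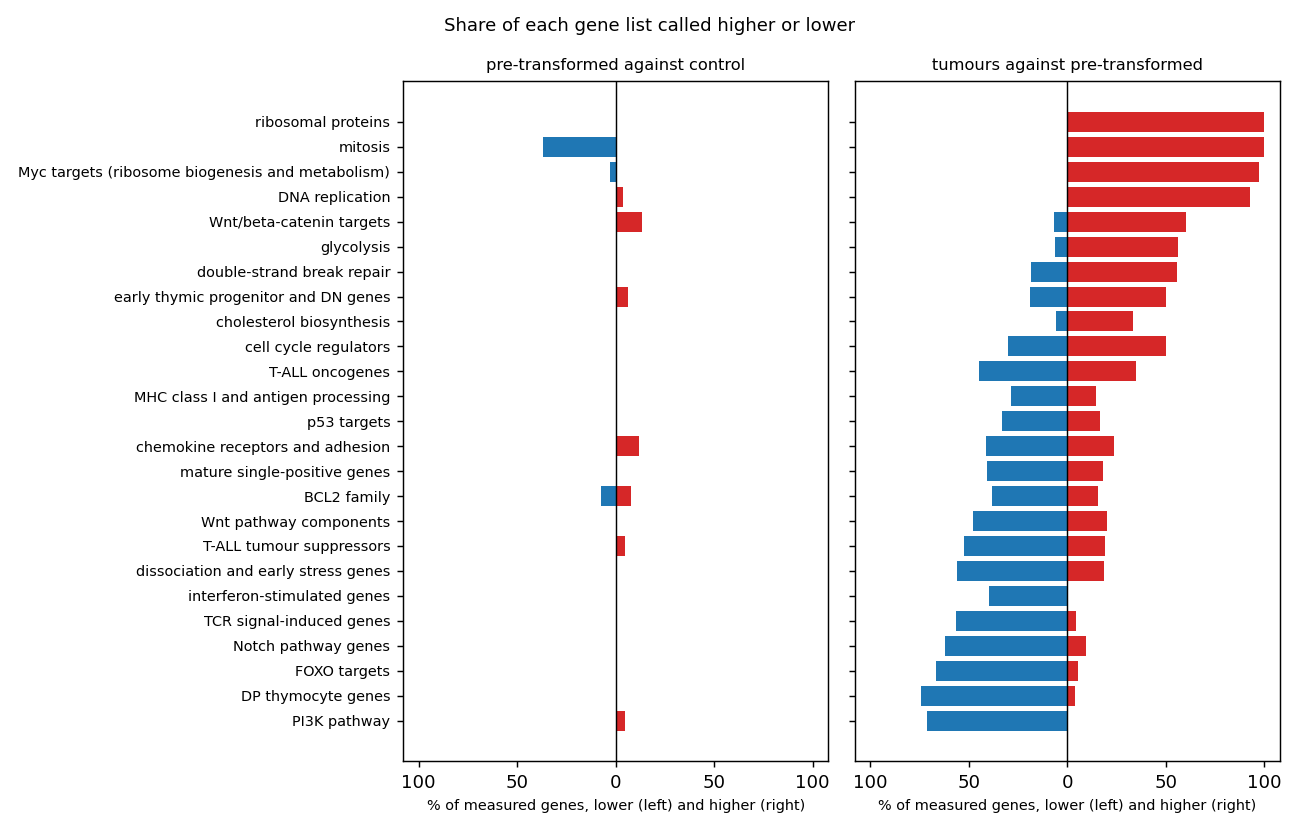
Percent of the measured members of 25 gene lists called higher (right) or lower (left) in pre-transformed against control DP thymocytes and in tumours against pre-transformed DP thymocytes. Mitosis genes were lower for 10 of 27 in the former and higher for 27 of 27 in the latter.

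Genes of the DP stage fell: 20 of 27 were lower and 1 higher, also adjusted over the list alone (median −1.03 relative to all genes, adjusted p = 3.18e-05, or adjusted p = 0.388 with an estimated correlation). The aquaporin gene Aqp11 went from 1142 to 54.7 (log2 change −4.38 ± 0.30 SE, adjusted p = 8.6e-06), Rag2 from 999 to 124 (adjusted p = 0.000275), Rag1 from 5360 to 1497 (adjusted p = 0.0107), and the CD3 gene Cd3e by a log2 change of −1.96. Dntt, which encodes terminal transferase, changed by −1.97 (adjusted p = 0.000413) and Bcl2l1, a survival gene of DP cells, by −1.89 (adjusted p = 0.00153). Over the alternatives the change of Bcl2l1 ran from −2.959 to −0.426, and its call was lost in 1 of them. The member that rose, named after its values were seen, was the fatty acid elongase gene Elovl6 (1.37, adjusted p = 0.0493). Of the coreceptor genes, Cd8a fell from 3843 to 2515 (log2 change −0.61, adjusted p = 0.0025) and Cd4 had a log2 change of 0.31 (adjusted p = 0.194).

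Notch pathway genes were lower in 13 of 21 and higher in 2, also adjusted over the list alone. The list missed the threshold of camera against other genes (adjusted p = 0.0658, or adjusted p = 0.396 with an estimated correlation). By fry, which tests whether members move on balance one way and not against other genes, it had an adjusted p of 0.000229. With 54.9% of genes called here, that result is not particular to this list. Other lists that camera did not call also passed by fry, such as T-ALL tumour suppressors (adjusted p = 0.00269) and Wnt pathway components (adjusted p = 0.00403). Notch3 fell by at least 2.91-fold (adjusted p = 0.00751) and the ubiquitin ligase gene Dtx1 by at least 1.54-fold (adjusted p = 0.00422), with Notch1 and Ptcra as above. Nrarp passed as lower with dim means in both groups (adjusted p = 0.028). Hes1, also dim in both groups, went the other way without passing (adjusted p = 0.0752), and was called higher in 2 of the alternatives. The members that rose, named after their values were seen, were Dtx4 (at least 1.29-fold) and Lfng, which was dim in both groups.

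Wnt targets rose in 9 of 15 and fell in 1, also adjusted over the list alone (adjusted p = 0.023, or adjusted p = 0.396 with an estimated correlation). With the common floor, chosen after seeing the data, 4 of 13 were higher and 0 lower. Apcdd1, a membrane inhibitor of Wnt signalling, went from 13.9 to 997, at least 22.8-fold (adjusted p = 6.34e-06), beside Myc. The member that fell, named after its values were seen, was Tcf7l2, dim in both groups. Axin2 had a log2 change of 0.33 (adjusted p = 0.276), and Nkd1 (adjusted p = 0.0166) and Notum (adjusted p = 0.00112) passed as higher with dim means in both groups. Wnt pathway components rose in 5 of 25 and fell in 12 (3 and 7 without pre-transformed 1 or 3; 5 and 12 also adjusted over the list alone, adjusted p = 0.167, or adjusted p = 0.629 with an estimated correlation).

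Genes of the PI3K pathway fell in 15 of 21 (16 adjusted over the list alone, adjusted p = 9.12e-05, or adjusted p = 0.388 with an estimated correlation). They act in opposite ways in the pathway: Pik3ip1 (log2 change −1.87) inhibits PI3K, whereas Pik3cd (675 to 100.2, −2.75) encodes a catalytic subunit and Insr (−2.34) a receptor. FOXO targets fell in 12 of 18 and rose in 1 (13 lower adjusted over the list alone, adjusted p = 0.00121, or adjusted p = 0.396 with an estimated correlation), with Gadd45a at −2.61 and Cdkn1b at −2.15. The exception, named after its values were seen, was the interleukin-7 receptor gene Il7r (at least 2.35-fold higher). TCR-induced genes fell in 13 of 23 and rose in 1, also adjusted over the list alone (adjusted p = 0.0108, or adjusted p = 0.396 with an estimated correlation), with Egr1 from 1343 to 102 and Cd6 at a log2 change of −2.06. Tox, named after its values were seen, was the member that rose (0.57, adjusted p = 0.0438). Genes of dissociation and early stress, which cell handling can raise and which share Egr1 with that list, were lower in 9 of 16 and higher in 3, or in 7 and 1 without pre-transformed 3 (adjusted p = 0.167, or adjusted p = 0.767 with an estimated correlation).

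T-ALL oncogenes were split, with 7 of 20 higher and 9 lower (4 and 7 without pre-transformed 3, 1 and 6 of 15 with the common floor, 3 and 11 with tumour 2 as the only tumour, 8 and 9 adjusted over the list alone; adjusted p = 0.892, or adjusted p = 0.929 with an estimated correlation), and their median of −0.41 and mean of 0.42 on the log2 scale, neither taken relative to all genes, differed in sign. Of 21 T-ALL tumour suppressors 11 fell and 4 rose, also adjusted over the list alone, or 12 and 2 with quantile normalization (adjusted p = 0.167, or adjusted p = 0.57 with an estimated correlation), with Runx1 at a log2 change of −2.14. Cdkn2a passed as higher and Mycn as lower with dim means in both groups (adjusted p = 0.0244 and 0.0282), and no size is given for them. Ikzf1 (0.18, adjusted p = 0.402), Bcl2 (−0.67, adjusted p = 0.234) and Lef1 (−0.13, adjusted p = 0.476) did not pass. Genes of early thymic progenitors rose in 8 of 16 (3 without pre-transformed 3, 2 of 9 with the common floor) and fell in 3, 8 and 3 also adjusted over the list alone (adjusted p = 0.0867, or adjusted p = 0.559 with an estimated correlation). Several of these, among them Spi1 and Csf1r, are also expressed by myeloid cells, and with tumour 2 as the only tumour 2 were higher and 4 lower.

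Markers of other blood cells moved with the tumour group, except in tumour 2. The lysozyme gene Lyz2 read 1659, 1376 and 1741 in tumours 1, 3 and 4 but 3.1 in tumour 2, and 42 to 89.6 in sorted cells. H2-Aa read 1382, 1058 and 1437 against 1.2 in tumour 2, and the B cell gene Ms4a1 198, 139 and 270 against 5. Of 19 myeloid markers 2 were called higher (1 adjusted over the list alone, list adjusted p = 0.023, or adjusted p = 0.767 with an estimated correlation), and 18 without tumour 2 and 13 with the common floor. B cell markers were higher in 5 of 9, or in 1 without pre-transformed 2 (adjusted p = 0.108), and stromal and endothelial markers in 4 of 10, or in 1 of 5 with the common floor (adjusted p = 0.0867). Tumour 2 kept Igfbp7 at 292.5, against 757 to 1545 in the other tumours. With tumour 2 as the only tumour, a choice made after seeing the data that assumes 1 array to vary like the others, 37 Myc targets, 27 mitosis genes, 25 replication genes and 22 ribosomal protein genes were higher and 18 PI3K genes lower, with 0 the other way in each. In that fit 11 glycolysis genes were higher and 2 lower, 6 Wnt targets higher and 2 lower, 21 DP genes lower and 1 higher, 11 Notch pathway genes lower and 3 higher, 13 FOXO targets lower and 1 higher, and 18 TCR-induced genes lower and 1 higher.

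**Figure D3:**
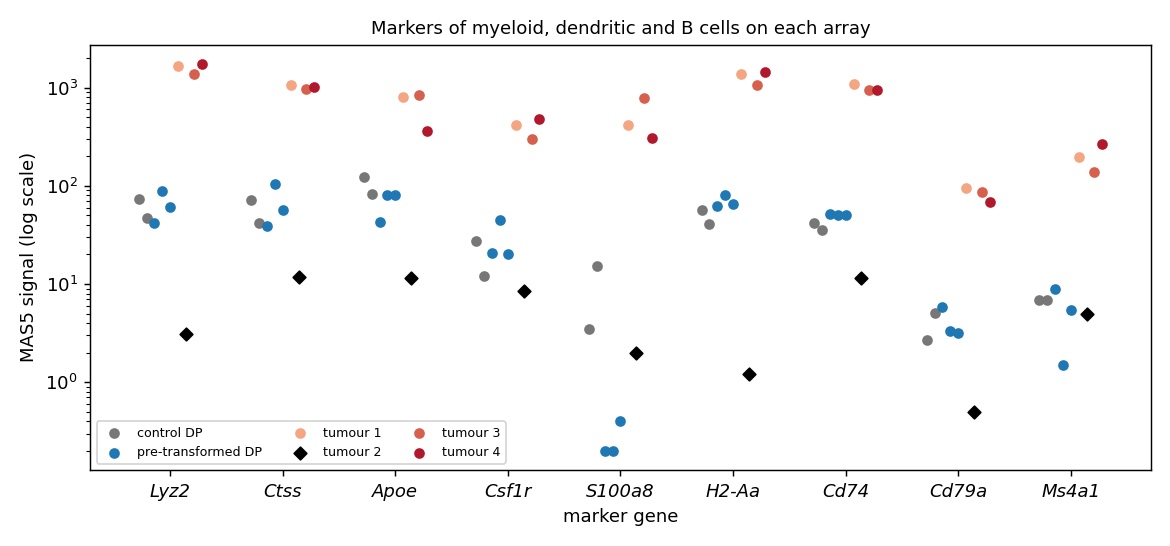
MAS5 signal (log scale) of Lyz2, Ctss, Apoe, Csf1r, S100a8, H2-Aa, Cd74, Cd79a and Ms4a1 on each array, with tumour 2 drawn as a black diamond. Lyz2 was 3.1 in tumour 2 and 1376 to 1741 in the other 3 tumours.

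Testing every probe set in place of 1 per gene raised the count of 6392 to 13168. Among 3433 called genes with more than 1 probe set, 350 had another probe set that went the opposite way.

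Tumours and control DP thymocytes were compared to ask how far tumours lie from normal DP cells and whether changes seen before transformation are found again in tumours. Wnt targets rose in 10 of 15 (6 without control 1, 6 without control 2, and 6 of 13 with the common floor), with Apcdd1 at least 24.4-fold higher and Axin2 2.13-fold higher (81.5, SD 0.31, n = 2, to 174, SD 0.44, n = 4; adjusted p = 0.01). Myc rose 19.2-fold (adjusted p = 2.89e-05), and Notch1 fell at least 20.4-fold from 731 (SD 0.07, n = 2; adjusted p = 8.81e-06). Cd44 rose from 61.4 to 984. Of the 190 genes changed before transformation, 40 that rose and 15 that fell moved the same way here, whereas the mitosis genes that had fallen were higher in tumours than in controls.

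In total 2387 genes rose and 2936 fell, 3728 of them by at least 2-fold, and with each array centred on its median 2808 rose and 2235 fell, the median of all genes moving from −0.08 to 0.13 on the log2 scale. The groups did not overlap for 7044 genes, where chance gives 13.3% of genes. The call for Wnt targets (10 also adjusted over the list alone, median 1.97 above that of all genes, adjusted p = 0.0016) had an adjusted p = 0.356 with an estimated correlation. Myc targets rose in 34 of 37 (34 adjusted over the list alone, adjusted p = 3.42e-16, or adjusted p = 0.356 with an estimated correlation). Mitosis genes rose in 25 of 27 (26 adjusted over the list alone, adjusted p = 1.01e-10, or adjusted p = 0.378 with an estimated correlation). Replication genes rose in 22 of 27 (8 without control 1, 22 adjusted over the list alone, adjusted p = 6.32e-08, or adjusted p = 0.378 with an estimated correlation). Ribosomal protein genes rose in 24 of 26 (13 without control 1, and 10 higher and 2 lower with quantile normalization, which lowered the list median from 0.745 to 0.223; 24 adjusted over the list alone, adjusted p = 1.69e-09, or adjusted p = 0.412 with an estimated correlation). DP genes fell in 19 of 27 (12 without control 1 or control 2, 20 adjusted over the list alone, adjusted p = 4.72e-05, or adjusted p = 0.356 with an estimated correlation). Notch pathway genes fell in 11 of 21 (5 without control 1, 12 adjusted over the list alone, adjusted p = 0.0324, or adjusted p = 0.378 with an estimated correlation). PI3K genes fell in 14 of 21 (14 adjusted over the list alone, adjusted p = 0.000134, or adjusted p = 0.356 with an estimated correlation). FOXO targets fell in 13 of 18 (13 adjusted over the list alone, adjusted p = 0.000284, or adjusted p = 0.356 with an estimated correlation). Cd4 rose here (log2 change 0.77, adjusted p = 0.0158) and Cd8a fell (−0.52, adjusted p = 0.0141). Tdrd5, a germ cell gene, fell at least 15.7-fold, and the mineralocorticoid receptor gene Nr3c2 rose at least 5.01-fold. Myeloid markers (2 of 19 higher, 19 without tumour 2, 0 without control 1, 8 with the common floor, 1 adjusted over the list alone; adjusted p = 0.0128, or adjusted p = 0.769 with an estimated correlation) and stromal markers (5 of 10 higher and 1 lower, also adjusted over the list alone, with 2 higher without control 1 or with the common floor; adjusted p = 0.0324, or adjusted p = 0.452 with an estimated correlation) moved with the group. With tumour 2 as the only tumour, a fit added after seeing the data, 9 Wnt targets were higher and 1 lower, 35 Myc targets and 27 mitosis genes higher and 0 lower, and 20 DP genes lower and 2 higher.

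Genes that rose before transformation and were higher in tumours than in controls included Cd44 (log2 changes 3.17 and 4.00), Cecr2 (at least 22.6-fold and 6.88-fold), Cadm4 (at least 1.67-fold and 9.52-fold), Prag1 (at least 4.32-fold and 3.28-fold) and Dact1 (at least 3.71-fold and 2.8-fold). Of these 40 genes 10 rose further between pre-transformed cells and tumours, 27 were not called there and 3, among them Cecr2 (log2 change −1.72), fell back. Of the 129 genes that rose, 27 were lower in tumours than in controls, such as Bcl2l2, dim in controls and in tumours, and 62 were not called. Independent lists would share 26.4 in the same direction and 32.5 in the opposite one. Of the 61 that fell, 15 were also lower in tumours, among them Nrp1 (at least 8.27-fold in tumours), Bmf (at least 6.56-fold) and Eya2 (at least 1.72-fold), and 25 were higher, among them Birc5 (log2 changes −1.07 and 1.29), Ccna2 (−1.05 and 0.94) and Cenpf (−0.87 and 1.61), where independent lists would give 15.4 and 12.5. Both comparisons share the control arrays. Groups simulated as unchanged against these controls, which hold next to no called genes by construction, shared 0.02 genes in the same direction on average (highest 1), where 55 were counted. They gave a correlation across genes of 0.503 where 0.20 was measured. The same sign was found in 64.2% of simulated genes and 46.3% of measured ones. The simulated tumours held no changes, whereas 45.7% of genes were called in tumours against control. Changes in tumours alone lower a correlation and a share of the same sign, so these measures cannot decide whether changes were shared. The simulated groups gave a covariance of 0.0896 where 0.167 was measured. With a different control for each comparison, a fit added after seeing the data that assumes 1 control array to vary like the others, 18 and 33 genes were called before transformation. Of these 6 and 8 were shared in the same direction and 2 and 4 in the opposite one, with covariances of 0.114 and 0.0203. Genes that rose thus exceeded the count of independent lists (40 against 26.4), whereas genes that fell did not (15 against 15.4). The excess of genes that rose, and that over the simulated count, is not separated here from the shared controls.

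**Figure D4:**
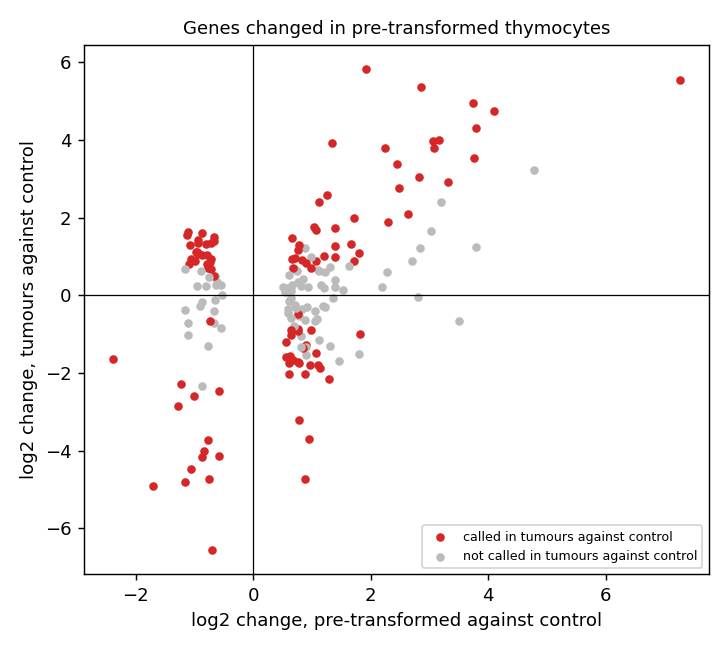
Log2 change in pre-transformed against control DP thymocytes (x axis) and in tumours against control DP thymocytes (y axis) for the 190 genes called in the former, red where also called in the latter and grey where not. Of the 129 genes to the right, 40 were called higher and 27 lower in tumours.

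The count of 5323 genes became 10555 with every probe set tested, 2577 without control 1 and 3166 without control 2. The 55 genes found again became 28 with no filter, 35 with a 2-fold minimum, 127 with array weights, 4 with the common floor and 1 without the trend. They became 9 without control 1, 7 without control 2 and 10 without pre-transformed 3. With other sets of arrays in the fit they became 6. There, pre-transformed against control was fitted on all arrays, and tumours against control on tumour and control arrays only, so both fits changed at once.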

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

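Except for the tests of array brightness, of a further marker list and of neighbours in another comparison, all tests in this part were chosen after the result was seen.

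Markers of other blood cells were high in tumours 1, 3 and 4 and low in tumour 2, with Lyz2 at 1659, 1376 and 1741 against 3.1. The median difference of tumour 2 from the other tumours was −0.00168 on the log2 scale over all genes tested. Each array had been scaled to a mean of 100, which removes a difference in brightness of a whole array. This value therefore cannot decide whether tumour 2 was dimmer, and shows only that its scaled values were not lower across the genes tested. Over all probe sets its median signal was 10.7, against 13.7 to 15.2 in the other tumours. A further list of myeloid and B cell genes, written before its values were seen, had 92.9% of its members (26 of 28) lower in tumour 2 than in every other tumour by at least 1 log2 unit, against 8.35% of all genes; 2 of the 28 are also in the fixed lists and 1 was bright (above 40.5) in sorted cells. These values are consistent with RNA of other blood cells in tumours 1, 3 and 4, which the tumours, having been collected without a sort, could hold. No biological explanation was tested.

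Notch1, Notch3, Dtx1 and Ptcra were lower and Myc higher in tumours than in pre-transformed cells. Dilution of DP cells by other cells is argued against by Cd4, Cd8a and Cd8b1, whose median change was −0.612 where Notch1 fell by 4.46 on the log2 scale. For Notch1 a fault of 1 probe set is argued against by its other bright probe set, at −3.344. For Notch3 and Dtx1 it is argued against by dimmer ones that fell from signals above the bacterial background, the smaller log2 change being −2.901. In tumours these probe sets read 10.6, 2.87 and 3.29, near or below the bacterial background of 7.8 to 13.9 there, so that the sizes are uncertain. Ptcra and Myc had 0 other probe sets past the filter, so that a fault of 1 probe set stays open for them. Labelling protocol, RNA input, sorting and age went with the group and cannot be told apart from transformation, and the β-actin 3′ to 5′ ratio did differ by 0.544. Chance as the source of the 6392 genes called in this comparison is argued against by the 35 splits of these 7 arrays. Only 1, the real one, gave as many, and the highest other gave 3556. A share of 1 in 35 is the smallest these splits can give, so chance is not excluded by them.

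Genes that rose in pre-transformed cells included pairs of chromosomal neighbours, among them Cecr2, Slc25a18 and Atp6v1e1 on chromosome 6 (at least 22.6-fold, at least 1.11-fold and a log2 change of 1.07). The 11 pairs exceeded random sets of genes (mean 1.41, highest 7, permutation p = 1e-04, the smallest that 10000 draws can give), which argues against a random placement of these genes. The draws took each gene independently, so they cannot decide on chance rises shared by neighbours whose values vary together. Pairs on 6 chromosomes argue against a single segment carried with a transgene as the source of all pairs. That count cannot decide whether such a segment raised the chromosome 6 genes alone, since pairs elsewhere do not bear on them. As many genes with the largest rise in tumours held 9 pairs, which is consistent with neighbours that rise together in other comparisons too, while the 61 genes that fell in pre-transformed cells held 1 pair. Whether Cre, its transgene or active β-catenin raised Cecr2 (log2 change 7.268, from a dim control mean) cannot be told apart, since no Cre-positive mouse lacked the β-catenin insert.

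Among 106 groups of 4 tumours tested for a value far from the others, 15 had one, where chance gives about 1 in 20, or 5.3, and in 12 tumour 2 was the lowest. Values below are the gap to the nearest tumour as a share of the range, both taken on the log2 scale. The readings given beside them for genes are linear signals. S100a8 (0.845) read 2 in tumour 2 and 309 to 776 in the others. Chil3 (0.861) read 2.4 in tumour 2 and 126 to 238 in the others. Gstm5 (0.847) read 3.5 in tumour 2 and 211 to 442.5 in the others. Notch3 (0.944) read 0.7 in tumour 2 and 14.7 to 17.6 in the others, below or close to the bacterial background of 7.8 to 13.9 on tumour arrays. Zfp820 (0.842) read 2.6 in tumour 4 and 0.2 to 0.3 in the others, all near background. List means, as log2 differences from controls, were lowest in tumour 2 for early progenitor genes (0.969; 1.01 against 2.44 to 2.48), T-ALL oncogenes (0.93; −0.29 against 0.99 to 1.08), FOXO targets (0.899; −1.60 against −1.21 to −1.17) and B cell markers (0.91; −1.48 against 2.50 to 2.90). They were also lowest there for markers of myeloid cells (0.932; −1.89 against 3.81 to 4.22), dendritic cells (0.965; 2.41 to 2.54 in the others), thymic epithelium (0.901; −0.96 against 0.24 to 0.38) and NK and innate cells (0.943; 0.13 against 2.20 to 2.33). Cell cycle regulators were lowest in tumour 1 (0.87; 0.03 against 0.49 to 0.56). Sex-linked genes were highest in tumour 4 (0.957, with 3.27 against 0.91 to 1.01), where Eif2s3y read 540.1 and Xist 11.8, the pattern of a male mouse. The other tumours had the pattern of females.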

How the results depend on the processing

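The common floor, tumour 2 as the only tumour and a different control for each comparison were chosen after seeing the data, and the floor was made common to all arrays after floors set per array had given results by construction. Of the planned and added settings, those not listed left each count within 1.5 times its value: 148 to 243 for pre-transformed against control (190), 4324 to 7124 for tumours against pre-transformed (6392), 3728 to 6666 for tumours against control (5323) and 52 to 78 for the genes found again (55).

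For pre-transformed against control the count became 74 with no filter, 1 with no trend, 431 with array weights, 82 with a 2-fold minimum, 6 with all 9 arrays in the fit, 15 with the common floor and 17 to 291 with 1 array left out. The genes found again became 28, 1, 127, 35, 6 and 4 in that order, 7 to 68 with 1 array left out, and 6 (control 1 for pre-transformed, control 2 for tumours) and 8 (the reverse) with a different control for each comparison. In the setting with all 9 arrays in the fit of pre-transformed against control, tumours against control was refitted on tumour and control arrays only. The count of genes found again there thus rests on a change of both fits. Every probe set gave 13168 for tumours against pre-transformed and 10555 for tumours against control, by testing more features, and leaving out 1 array gave 5123 to 6559 and 2577 to 5710. A 2-fold minimum lowers a count by construction, and for the other settings the cause was not tested.

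Directions reversed for 3 named values: Tpx2 in pre-transformed against control was 0.307 with the mean of probe sets, Bcl2l1 in tumours against control 0.024 with the mean of probe sets, and Ikzf1 in tumours against pre-transformed −0.333 with tumour 2 as the only tumour. The cause was not tested. Of 20 named genes called in pre-transformed against control 1 stayed called in all settings, of 37 in tumours against pre-transformed 25, and of 37 in tumours against control 20. With replicate number as a block, pre-transformed against control gave 148 genes, but correlations of arrays that share a number (−0.024 to 0.085) lay near those that do not (−0.085 to 0.062). Signals near the background, which was 2.4 to 5 on sorted arrays and 7.8 to 13.9 on tumour arrays, limit folds to lower bounds. With no filter the median change of all genes was 0.278 on the log2 scale in tumours against pre-transformed cells and 0.358 against controls. With the main filter these medians were −0.121 and −0.077.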

Other observations

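No test in this part goes beyond those of the comparisons, and Malat1 was chosen after its values were seen. Interferon-stimulated genes were lower in 8 of 20 in tumours against pre-transformed cells (7 adjusted over the list alone, 5 without pre-transformed 2 or 3), with the transcription factor gene Irf9 falling from 174 to 51.7, and the list was not called (adjusted p = 0.121, or adjusted p = 0.804 with an estimated correlation). Between pre-transformed and control cells limma called 0 of these 20, with 4 higher at an unadjusted p under 0.05 and a list median of 0.48 on the log2 scale (adjusted p = 0.0785, or adjusted p = 0.715 with an estimated correlation). In tumours against pre-transformed cells, the comparison of all further counts here, cholesterol synthesis genes rose in 6 of 18 and fell in 1 (adjusted p = 0.0658, or adjusted p = 0.804 with an estimated correlation), with Sqle from 69.5 to 369 and Idi1 from 100.3 to 467. With tumour 2 as the only tumour, a fit chosen after seeing the data, 16 were higher. MHC class I and antigen processing genes rose in 2 of 14 and fell in 4, with 7 lower without tumour 1 and 11 lower with tumour 2 as the only tumour (adjusted p = 0.336).

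In the same comparison, tumours against pre-transformed cells, genes of mature single-positive cells rose in 4 of 22 and fell in 9, or in 5 without pre-transformed 1 or 3 (adjusted p = 0.558), p53 targets rose in 3 of 18 and fell in 6, or in 7 and 6 without tumour 2 and 6 and 4 with median centring (adjusted p = 0.892), BCL2 family genes rose in 2 of 13 and fell in 5, or in 8 with tumour 2 as the only tumour (adjusted p = 0.524), and genes of chemokine receptors and adhesion rose in 4 of 17 and fell in 7 (adjusted p = 0.524). Dendritic cell markers rose in 1 of 11 and fell in 1, or in 9 and 1 without tumour 2 (adjusted p = 0.261), thymic epithelial markers fell in 2 of 6 (adjusted p = 0.892), erythroid markers rose in 1 of 3 and fell in 1 (adjusted p = 0.684), and NK and innate markers rose in 3 of 10 and fell in 2, or in 8 and 2 without tumour 2 (adjusted p = 0.236). Of 4 sex-linked genes limma called 0 in that comparison, and 0 had an unadjusted p under 0.05, while 1 did in pre-transformed against control. The nuclear transcript Malat1 read 144, 82.5, 134 and 104 in tumours 1 to 4 and 3112 to 4938 in sorted cells, a log2 change of −5.10 against pre-transformed cells. Eif2s3y, a Y-linked gene, read 614.5 in pre-transformed 1 and 540.1 in tumour 4, where Xist read 12.6 and 11.8. On all other arrays Eif2s3y read 0.3 to 8 and Xist 4086.5 to 5445.5. The pre-transformed and tumour groups thus held both sexes and the control group females only.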
